A study of Mus musculus with 15 samples.

How the data were processed

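The series holds 15 RNA-seq libraries of mouse small intestinal epithelium in 5 groups of 3. Groups and replicate numbers came from the sample titles. The 9 organoid libraries stood in a table of 27179 rows and the 6 libraries of sorted cells in another of 24594 rows. Per the file headers, the in vivo table has a column of Entrez gene identifiers and one of symbols, and 7 of its rows lack a symbol. The organoid table has a column per library and no gene identifiers, so 0 of its rows could be given a gene name, and no name was inferred from the order or the values of its rows. Yap1, the YAP transgene, named genes and gene lists were therefore not analysed here in the organoids.

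The deposited values of both tables are whole-number counts that the authors did not normalize, as read from the values. The submitters' processing notes name the mouse build mm10 and edgeR for all libraries, and featureCounts for the organoid libraries. The aligner, the annotation, the strand setting, the filters and the tool versions are not given in the sources used here. Per the labels' protocols, the fetal organoid libraries were made with a TruSeq RNA kit and the adult in vivo libraries with a stranded total RNA kit for very low input. The library kits of the other groups are not given in the sources used here. Per the labels, adult crypt cells of the first 20% of the small intestine were sorted as EpCAM-positive, lineage-negative cells with a middle level of CD24, and fetal cells as EpCAM-positive, CD31-negative and CD45-negative cells. Sort gate and age therefore changed together in vivo, and genotype changed with age in the organoids. Y-linked genes had counts in the fetal and 0 counts in the adult in vivo libraries, so sex composition changed with age there too.

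Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr by group, group means and no other term. The 3 organoid groups were fitted together and share the estimate of the spread, and the 2 in vivo groups were fitted by themselves. A gene or row was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. It is an approximation and can be too small for genes with few counts in a group. For some of these, leaving out a library moved the fitted log2 by more than this error. CPM values were scaled by the TMM-adjusted library size and are given as mean ± SD of 3 libraries. Rn45s, a ribosomal RNA precursor, was kept as a gene and took 7.32% to 10.7% of the counts of an in vivo library. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is a lower bound. With 1 to 3 counts in a group, the ratio is given with its exact 95% counting interval in parentheses. Floors and intervals cover counting error only.

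Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over lists. The 35 lists and the rule for named genes were fixed before the data were examined. Of the 654 symbols of the lists, 633 were found in the in vivo table and 514 were tested. The rule names a fixed set of key genes, the 8 genes with the largest positive and the 8 with the largest negative log2 fold change, and up to 4 called members of each list with the smallest p. The 8 genes per direction had to be called, have an average log2 CPM of at least 3, show no overlap between the groups (10% by chance) and carry no predicted or clone name. The text and figures give some of the key genes and list members that the rule names. The list of mitochondrially encoded genes had 0 members in the table and was not tested. Coordinates are those of the RefSeq annotation of mm10, matched on the Entrez identifier for 99.95% of the tested in vivo genes. Reads of near-identical or overlapping genes can be split or shared, so values of Hspa1a and Hspa1b, Reg3b and Reg3g, Akp3 and Alpi, the H2 and hemoglobin genes, and Mir675, which lies inside H19, are uncertain.

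The procedure was tested on simulated counts. All groups were drawn from the means of the second-named group of a comparison, with the real library sizes and a dispersion shared by the groups. Each fold was given to 90 to 99 of the tested rows, whereas 54.9% to 65.8% of rows were called in the data. The rates that follow hold for few changed rows and equal spread, and were not tested under the conditions of the data. It recovered 40% of the 2-fold and 89.1% of the 4-fold changes between DOX and no DOX over 14009 rows, 50.5% and 90.4% between fetal and adult organoids over 14006 rows, and 43.5% and 89.4% between fetal and DOX organoids over 13785 rows. In vivo it recovered 89.6% and 100% over 12209 genes. False calls were 2.44%, 4.26%, 8.15% and 7.37% of the calls in the same order.

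Alternatives were RLE size factors, library size only, DESeq2 1.42.0, no filter on low counts, each library left out, the replicate number as a block and, for organoids, a fit of only the 2 groups compared. Planned tests that join both tables by gene were not run, because the organoid rows carry no identifiers. These were the difference between the fetal-adult change in culture and in vivo, and the tests of in vivo fetal and adult gene sets in the organoid changes.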

Results

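RNA-seq counts were collected from mouse proximal small intestinal epithelium in 5 groups of 3 libraries. Sorted epithelium of E16.5 fetuses and sorted adult crypt epithelium were profiled directly. Organoids grown from E16.5 epithelium, with 3 fetuses pooled per sample, were profiled beside adult organoids. The adult organoids carried a human YAP transgene under a doxycycline (DOX) switch and were cultured with or without DOX. YAP is the transcriptional coactivator held in check by the Hippo pathway. The design asks how fetal and adult epithelium differ and what YAP induction changes in adult organoids.

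Total counts were 12724510 to 36977226 per organoid library and 5795518 to 10538004 per in vivo library. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 4.18, so each was counted as a sample. The labels do not say for every group that replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical in part. The biological coefficient of variation was 5.59% in fetal organoids, 8.31% with DOX, 9.85% in fetal and 11.3% in adult sorted cells. It was 35.2% in organoids without DOX, where replicate 3 stood apart, and 4.29% without that library.

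The fetal libraries were set apart from those of adult crypt epithelium by growth genes of the embryo. H19, an imprinted noncoding RNA (Entrez 14955, chromosome 7, 142575530 to 142578146 in mm10), stood at 21963 ± 2509 CPM (SD, n = 3) in fetal cells and had 0 counts in adult cells, at least 126101-fold higher. Its neighbour Igf2, a fetal growth factor (Entrez 16002, chromosome 7, 142650768 to 142666816), was at 4910.1 ± 292 against 1.91 ± 1.08 CPM. Of the 18 tested oncofetal and imprinted growth genes, 17 were higher in fetal cells and 1 was lower (camera adjusted p = 5.16e-62, and adjusted p = 0.0198 with an estimated correlation). The fetal sort took EpCAM-positive cells, a gate meant to leave out mesenchyme, yet mesenchyme genes were higher in the same libraries (218 against 5.62 CPM in sum), and whether such cells carried any of this rise was not tested. Cdkn1c, an imprinted cell cycle inhibitor, was higher by a log2 fold change of 6.70 ± 0.14 (SE) and Igf2bp1, an RNA-binding protein of fetal tissue, by 9.96 ± 0.24, or 11.23 without adult replicate 3. Lin28b, which blocks let-7 maturation, was at 3.61 ± 1.06 CPM over 2 adult counts, a ratio of 30.5 (8.21 to 255), with a fitted log2 of 4.76 ± 0.70 that was 7.78 without adult replicate 1. In all, 7304 of 13314 tested genes differed, 3859 higher and 3445 lower in fetal cells (edgeR quasi-likelihood test). Changes over 2-fold numbered 2124 higher and 1059 lower, and changes over 8-fold 847 and 223.

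Other genes at the top of the fetal side had 0 counts in the 3 adult libraries. Trim71, a let-7 target of the early embryo, was at least 1030.5-fold higher, Mir675 at least 972-fold, Obsl1 at least 544-fold, Tfec at least 524-fold, the folate receptor Folr1 at least 502-fold and DQ267101 at least 447-fold. Cym, the milk-clotting protease of the infant stomach, was at least 708-fold higher, but stood at 23.2, 20.7 and 273 CPM in fetal replicates 1 to 3. Its fitted log2 was 12.63 ± 2.43, and 10.20 without fetal replicate 3. On the adult side, Ido1, a tryptophan-degrading enzyme, had 0 fetal counts and was at least 525-fold lower in fetal cells. The intestinal phosphatase Akp3 was lower, with a log2 fold change of −8.19 ± 0.21. Ces1f had 2 fetal counts, an adult-to-fetal ratio of 379 (104 to 3135). Car4, a carbonic anhydrase, had 1 fetal count, a ratio of 1212 (217 to 47933), and Rbp7 had 1, a ratio of 503 (89.6 to 19916). Their fitted log2 values of −9.70 ± 0.34 and −8.44 ± 0.43 were −11.24 and −9.97 without fetal replicate 3.

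Genes of crypt stem cells and of Wnt signalling were lower in fetal epithelium. Of 20 stem cell markers 19 were lower, led by Olfm4 at 90.8 ± 15.2 against 7474 ± 1240.0 CPM (log2 fold change −6.36 ± 0.18). Aqp4, Smoc2 and Rgmb had log2 fold changes of −3.23 ± 0.12, −3.12 ± 0.14 and −2.67 ± 0.10. Lgr5, the Wnt-amplifying receptor of crypt base stem cells, was at −2.04 ± 0.21 and Ascl2, a Wnt-driven stem cell factor, at −2.32 ± 0.24. Of 12 Wnt targets 11 were lower, among them Axin2 at −3.03 ± 0.14, Cd44 at −3.26 ± 0.15 and Ccnd1 at −1.98 ± 0.12. Both lists passed camera (adjusted p = 1.52e-20 and 4.72e-09). Each had adjusted p = 0.136 with an estimated correlation. Of 24 DNA replication and mitosis genes 19 were lower, or 20 adjusted over the list alone, with Top2a at −1.21 ± 0.12 and Mki67 at −0.86 ± 0.11 (camera adjusted p = 0.00363, and adjusted p = 0.553 with an estimated correlation). The adult sort took crypt cells with a middle level of CD24, so gate and age differ together in each of these groups.

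Immune defence genes were also lower in fetal epithelium. All 18 antigen presentation genes were lower, with Cd74, the class II invariant chain, at 0.291 ± 0.0722 against 608 ± 184 CPM (log2 fold change −10.91 ± 0.32). H2-Ab1 and H2-Eb1 had log2 fold changes of −7.20 ± 0.30 and −8.05 ± 0.36, the immunoproteasome subunit Psmb8 of −5.77 ± 0.17 and the peptide transporter Tap1 of −3.17 ± 0.13 (camera adjusted p = 1.61e-27, and adjusted p = 0.0999 with an estimated correlation). Immune cell markers, of which 3 could be tested, summed to 20.5 CPM in fetal and 21.0 CPM in adult cells. Itgam was lower (−1.84 ± 0.24), Csf1r was higher (0.71 ± 0.18) and Laptm5 was higher with a ratio of 17.1 (5.63 to 84.6), and the list did not pass (adjusted p = 0.932). Of 14 antimicrobial and mucosal defence genes 10 were lower and 1 was higher (camera adjusted p = 3.63e-16, and adjusted p = 0.0198 with an estimated correlation). The IgA transporter Pigr was at 46.1 ± 6.29 against 8270.4 ± 918 CPM, a log2 fold change of −7.48 ± 0.16, and the lectins Reg3g and Reg3b were at −7.96 ± 0.16 and −6.51 ± 0.33. Of 18 interferon response genes 11 were lower, or 12 adjusted over the list alone, and 2 higher, with Oasl2 at −4.38 ± 0.20 and Irf9 at −1.41 ± 0.12 (camera adjusted p = 3.60e-04, and adjusted p = 0.170 with an estimated correlation).

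The lists of suckling-type and adult-type enterocyte genes changed in opposite directions. The adult sort took crypt cells with a middle level of CD24, so gate and age differ together in the enterocyte lists. All 12 fetal and suckling-type genes were higher in fetal cells (camera adjusted p = 1.94e-13, and adjusted p = 0.0276 with an estimated correlation). Prdm1, a repressor of the adult enterocyte programme, was higher by 5.58 ± 0.15, the lactase Lct by 2.59 ± 0.15 and the galactosidase Glb1 by 2.90 ± 0.11, and the endocytic receptor Lrp2, with 0 adult counts, was at least 355-fold higher. Of 11 adult-type genes 9 were lower and 0 higher, or 1 higher adjusted over the list alone (camera adjusted p = 6.82e-12, and adjusted p = 0.0198 with an estimated correlation). The sucrase Sis was at −4.06 ± 0.21, Clca4b at −2.74 ± 0.17 and the arginase Arg2 at −7.87 ± 0.19, or −8.50 without fetal replicate 3. Of 27 absorption and brush border genes 18 were higher and 7 lower, with the apolipoprotein Apoa1 at 2.48 ± 0.12, the vitamin B12 receptor subunit Cubn at 3.39 ± 0.13 and the phosphatase Alpi at 0.77 ± 0.14 (camera adjusted p = 2.38e-04, and adjusted p = 0.354 with an estimated correlation). Of 19 cholesterol synthesis genes 17 were higher and 0 lower, with Insig1 at 1.99 ± 0.14 (camera adjusted p = 2.15e-04, and adjusted p = 0.375 with an estimated correlation).

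**Figure D1:**
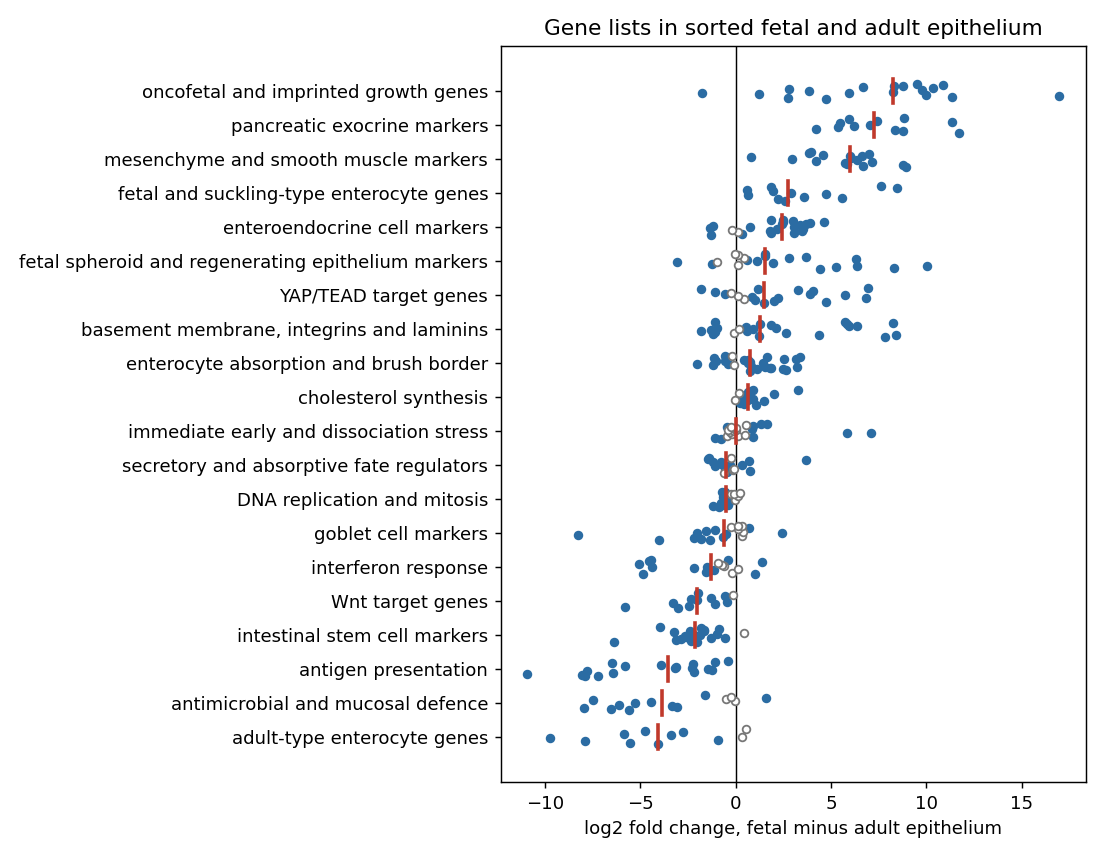
Log2 fold change (fetal minus adult) of each tested gene of the fixed lists that passed camera at the preset correlation and had at least 10 tested genes; filled points were called, open points were not, red bars are medians, and genes with 0 counts in a group stand at their bound. Oncofetal genes have a median of 8.28 and adult-type enterocyte genes a median of −4.06.

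Yap1 itself was not called different. It stood at 136 ± 8.44 CPM in fetal and 143.6 ± 10.501 CPM in adult cells, a log2 fold change of −0.08 ± 0.09 (edgeR adjusted p = 0.487). Of 19 YAP/TEAD target genes 13 were higher and 3 lower in fetal cells (camera adjusted p = 9.77e-04, and adjusted p = 0.136 with an estimated correlation). Ccn2, a matricellular YAP target, was higher by 4.72 ± 0.34, Ccn1 by 1.51 ± 0.28, Ptpn14 by 4.06 ± 0.22 and Amotl2 by 2.02 ± 0.13, and the receptor kinase Axl, with 0 adult counts, was at least 113-fold higher. Ankrd1 had 12 fetal and 0 adult counts and was not tested. Of 24 Hippo pathway components 10 were higher and 4 lower, with Amotl1 at 2.88 ± 0.15 and Vgll4 at −1.45 ± 0.12, and the list did not pass (adjusted p = 0.235). Of 20 fetal spheroid and regeneration markers 13 were higher and 2 lower, or 3 lower adjusted over the list alone (camera adjusted p = 1.14e-04, and adjusted p = 0.134 with an estimated correlation). Clu, a marker of regenerating crypts, was higher by 5.24 ± 0.24 and Emp1 by 2.79 ± 0.11, and Ly6e was lower (−3.08 ± 0.11). Gja1 had a ratio of 408 (72.9 to 16137) over 1 adult count, and its fitted log2 of 8.29 ± 0.47 was 10.48 without adult replicate 2. Ly6a had 8 fetal and 26 adult counts and was not tested. Of 24 basement membrane, integrin and laminin genes 16 were higher and 6 lower, with Lamb1 at 8.41 ± 0.23, Lama5 at 4.36 ± 0.15 and Lamc1 at 2.65 ± 0.11 (camera adjusted p = 8.53e-06, and adjusted p = 0.0443 with an estimated correlation). All 17 mesenchyme genes were higher in the same libraries (218 against 5.62 CPM in sum), despite the EpCAM gate, and whether such cells carried any of the changes of this paragraph was not tested.

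Lists of secretory cells held calls in both directions, and no test between lineages was run. The adult sort took crypt cells with a middle level of CD24, and the labels give no CD24 gate for the fetal sort. Gate and age therefore differ together in each of these lists. Of 23 enteroendocrine genes 18 were higher in fetal cells and 3 lower, with the transcription factor Pax6 at 3.72 ± 0.18, the prohormone-processing enzyme Cpe at 2.46 ± 0.12 and the granule protein Chga at −1.31 ± 0.11 (camera adjusted p = 3.47e-07, and adjusted p = 0.206 with an estimated correlation). In fetal replicate 2, 21 of the 23 lay above the mean of replicates 1 and 3 (median 0.28), beside the pancreatic exocrine genes (median 0.96). A share of pancreatic cells in the rise was not tested. Of 18 goblet genes 10 were lower and 2 higher, or 3 higher adjusted over the list alone, with Zg16 at −8.28 ± 0.36, the mucin Muc2 at −4.03 ± 0.25 and Ccl9 at 2.42 ± 0.15 (camera adjusted p = 0.0195, and adjusted p = 0.582 with an estimated correlation). Without fetal replicate 1 the goblet list did not pass (adjusted p = 0.0666, range over settings 2.37e-06 to 0.582). Of 14 Paneth genes 7 were lower and 4 higher and the list did not pass (adjusted p = 0.0757), with the lysozyme Lyz1 at −3.14 ± 0.20 and Clps, which the pancreas also makes, at 4.53 ± 0.33. It passed without adult replicate 1 or 2 (adjusted p = 0.0259 and 0.0475, range over settings 0.0259 to 0.553). Of 5 tuft cell genes 3 were lower and 1 higher (adjusted p = 0.253), with Plcg2 at −2.10 ± 0.18, and Dclk1, with 28 fetal and 10 adult counts, was not tested. Of 20 fate regulators 12 were lower, or 13 adjusted over the list alone, and 4 higher, with Hnf4a at −1.06 ± 0.09 and Elf3 at −1.17 ± 0.09 (camera adjusted p = 0.0195, and adjusted p = 0.200 with an estimated correlation).

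**Figure D2:**
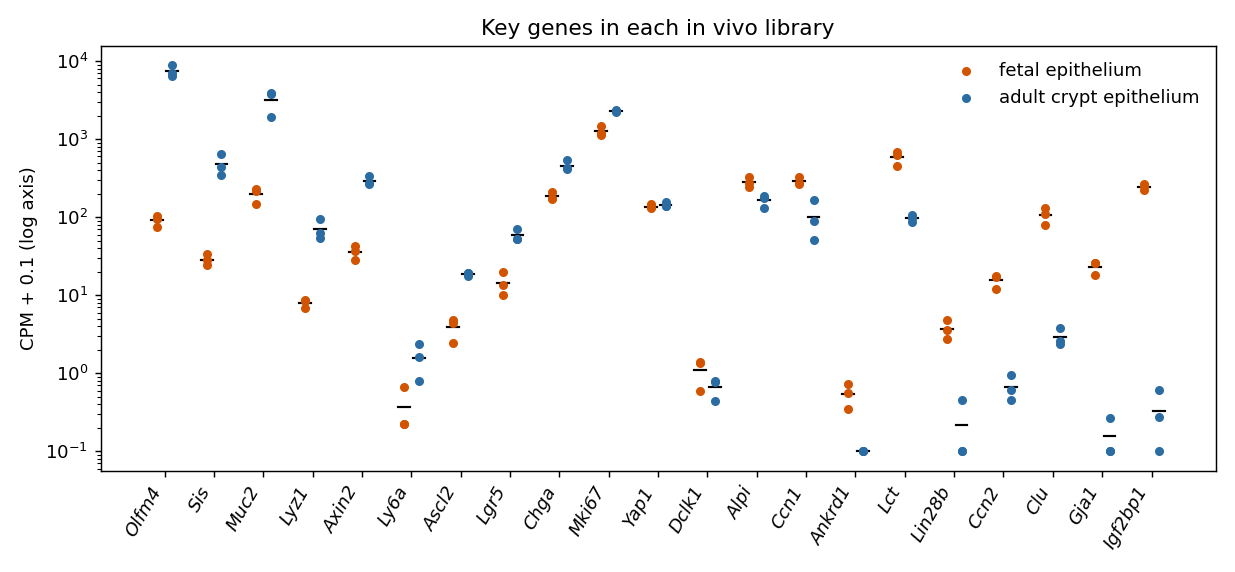
CPM plus a small constant of key genes on a log axis in each of the 6 in vivo libraries, with group means as bars. Olfm4 averaged 90.8 CPM in fetal and 7474 CPM in adult libraries, and Igf2bp1 247 and 0.231 CPM.

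Markers of other cell types were mostly higher in fetal libraries. All 12 pancreatic exocrine genes were higher and summed to 1264 CPM against 4.08 CPM (camera adjusted p = 1.10e-13, and adjusted p = 0.170 with an estimated correlation). Ctrb1, a digestive protease precursor, stood at 365, 786 and 329 CPM in fetal replicates 1 to 3 and the carboxypeptidase Cpa1 at 179.9, 396 and 176 CPM. Their ratios were 2759.6 (944 to 13383) and 4220.4 (757 to 166723), and their fitted log2 values of 11.34 ± 0.57 and 11.71 ± 0.64 were 12.21 and 13.90 without adult replicate 2. In fetal replicate 2 the pancreatic genes lay above the mean of replicates 1 and 3 by a median of 0.96 on the log2 scale. All 17 mesenchyme genes were higher and summed to 218 against 5.62 CPM, with Sparc at least 128-fold higher over 0 adult counts (camera adjusted p = 2.14e-10, and adjusted p = 0.136 with an estimated correlation). All 5 erythroid genes tested were higher, with Hbb-bt at 23.8 ± 5.68 CPM over 0 adult counts (camera adjusted p = 8.19e-04, and adjusted p = 0.206 with an estimated correlation). All 5 neuron and glia genes tested were higher, with Ret at 3.56 ± 0.23 (camera adjusted p = 0.00328, and adjusted p = 0.166 with an estimated correlation). The 1 mesothelium gene tested, Upk3b, stood at 33.6 ± 2.55 CPM over 2 adult counts, a ratio of 294 (81.1 to 2429) (camera adjusted p = 0.00129, and adjusted p = 0.133 with an estimated correlation). Of 7 gastric genes 6 were higher and the list did not pass (adjusted p = 0.118), but it passed without fetal replicate 2 (adjusted p = 0.0472) and with the replicate block (adjusted p = 0.0395, range over settings 0.0395 to 0.578). Tff1 stood at 2.49, 2.24 and 19.2 CPM in fetal replicates 1 to 3, a ratio of 158 (28.0 to 6249.6) over 1 adult count, and its fitted log2 of 6.80 ± 1.43 ran from 4.97 to 9.003 over the left-out libraries. Of 3 endothelial genes 2 were higher and 1 was lower, Esam at −2.99 ± 0.38 (adjusted p = 0.874, list median 0.66, mean −0.43, test direction lower).

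Stress and metabolism lists gave mixed changes. The heat shock genes Hspa1a and Hspa1b were higher in fetal cells by 7.10 ± 0.28 and 5.84 ± 0.19, within an immediate early and dissociation stress list of 7 higher and 3 lower of 21 (camera adjusted p = 0.0316, and adjusted p = 0.618 with an estimated correlation). Without adult replicate 3 this list did not pass (adjusted p = 0.265, range over settings 0.00288 to 0.618), and its median moved to −0.21 from 0.04. Of 17 integrated stress response genes 11 were higher, with Psat1, a serine synthesis enzyme, at 1.46 ± 0.13, and the list did not pass (adjusted p = 0.0696). It passed without fetal replicate 3 or adult replicate 2 and with the replicate block (adjusted p = 0.0332, 0.0464 and 0.0480, range over settings 0.0332 to 0.578). Of 24 cytoskeleton and tight junction genes 9 were higher and 10 lower, with Cldn15 at −2.50 ± 0.09 (adjusted p = 0.171, median −0.01, mean 0.37, test direction lower). Of 20 xenobiotic and glutathione genes 6 were higher, or 7 adjusted over the list alone, and 9 lower, with Cyp4f14 at −3.78 ± 0.19 and Gstm1 at 1.52 ± 0.11 (adjusted p = 0.293). Of 16 p53 targets 6 were higher, or 8 adjusted over the list alone, and 4 lower, with Plk2 at 4.15 ± 0.29 (adjusted p = 0.650). Of 7 patterning genes 3 were higher and 3 lower, with Osr2 at −3.10 ± 0.33 and Onecut2 at 0.63 ± 0.08 (adjusted p = 0.532). Where no second count is given, the counts adjusted over the list alone equalled those over all genes.

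In the organoids, DOX and no DOX differed in 8785 of 14877 tested rows, 4134 higher and 4651 lower with DOX, of which 5341 moved over 2-fold (edgeR quasi-likelihood test). The organoid rows carry no gene identifiers, so the changed genes are not named here and the level of the transgene was not checked. The series has no DOX-treated organoids without the transgene, so effects of DOX itself were not told apart from those of YAP. Fetal organoids differed from adult organoids without DOX in 8393 rows, 4048 higher and 4345 lower, of which 5430 moved over 2-fold. They differed from adult organoids with DOX in 9785 rows, 5267 higher and 4518 lower, of which 6603 moved over 2-fold. With library size only, calls split into 2672 higher and 6775 lower for DOX, 4873 and 3447 for fetal against no DOX, and 7908 and 2811 for fetal against DOX. Under that scaling the medians of all rows were −0.47, 0.18 and 0.67 on the log2 scale, against −0.08, −0.02 and 0.08 with TMM, so directions are relative to the scaling.

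Fetal organoids stood farther from both adult groups than these from each other. Correlations of log2 CPM between libraries averaged 0.734 for fetal and no-DOX organoids, 0.745 for fetal and DOX organoids and 0.880 for DOX and no DOX, across rows, which are not independent replicates. The order of the values for fetal organoids rested on no-DOX replicate 3, at 0.697 to 0.701, as no-DOX replicates 1 and 2 gave 0.748 to 0.755 and DOX libraries 0.741 to 0.748. The first principal component, with 67.9% of the variance, placed fetal libraries at −168.0 to −166.4, no-DOX libraries at 71.8 to 86.3 and DOX libraries at 89.6 to 90.6. The second, with 25.6%, placed DOX libraries at 81.4 to 89.7, no-DOX libraries at −113.0 to −77.9 and fetal libraries between them at 2.76 to 5.48. Genotype differs with age in the organoids, and the library kit may differ too.

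**Figure D3:**
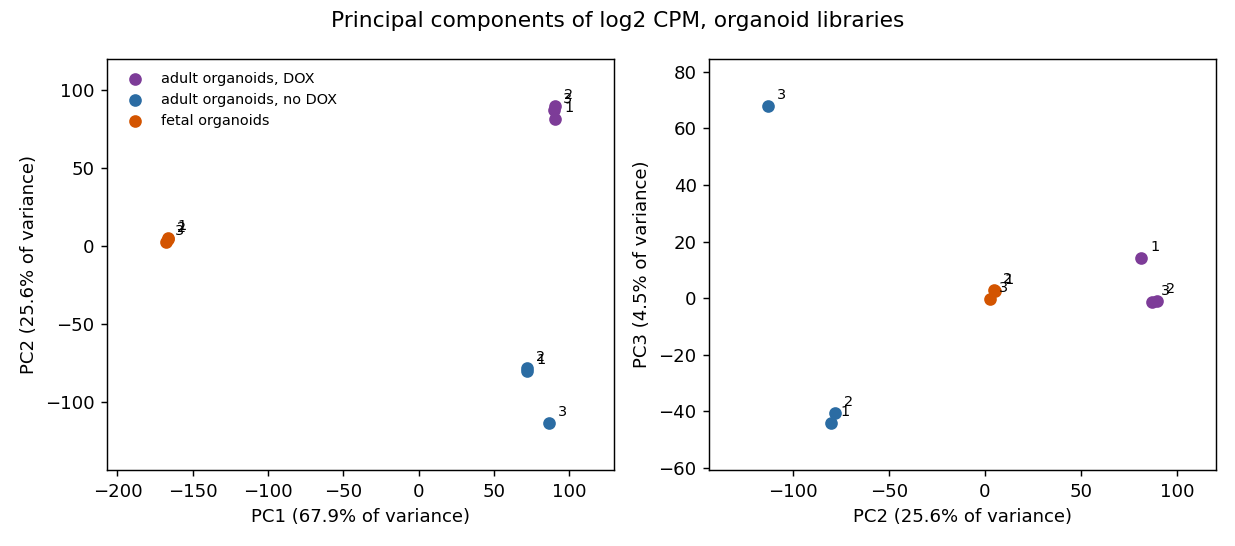
Principal components of log2 CPM of the 9 organoid libraries, with the replicate number beside each point. Component 1 parts fetal from adult organoids, component 2 parts DOX from no DOX, and component 3 (4.55% of the variance) parts no-DOX replicate 3 from replicates 1 and 2.

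Rows called in both the DOX and the fetal comparison against no DOX moved the same way in 64.3% of cases. Of them 1701 were higher in both and 1723 lower in both, beside 1124.9 and 1358.4 for independent lists, while 1094 were higher with DOX and lower in fetal organoids and 804 the reverse, beside 1207.4 and 1265.5. Of the 8393 rows called between fetal and no-DOX organoids, 40.8% were called in the same direction with DOX, 22.6% in the opposite direction, and 3071 were not called with DOX. Of the 3424 rows with a shared direction, 1886 differed between fetal and DOX organoids, and in 837 of these the DOX value lay beyond the fetal value. These counts rest on the spread shared by the 3 groups. Without no-DOX replicate 3, the shared direction covered 58.1% of rows called in both. Then 2371 rows were higher in both and 2494 lower in both, or 44.3% of the fetal calls, and rows with opposite directions rose from 1898 to 3503, or 31.9%. The changes had a Pearson correlation of 0.312 and a covariance of 1.35 across rows, or 0.260 and 0.814 for rows with an average log2 CPM of at least 3, for which the draws that follow were not made. Both comparisons share the no-DOX libraries, and in 30 simulated draws with no changed group the correlation averaged 0.507 and the covariance 0.0435. In 30 further draws with the spread of each group, added after that result was seen, they averaged 0.878 and 0.1004. The difference in covariance was 1.303 and 1.246. The draws had at most 0 and 16 rows called in both with the same direction, in the same order, but no group was changed in them. With 3 controls no split leaves 2 on each side, and the overlap was not tested with separate controls. Part of the excess overlap may therefore come from the shared controls.

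**Figure D4:**
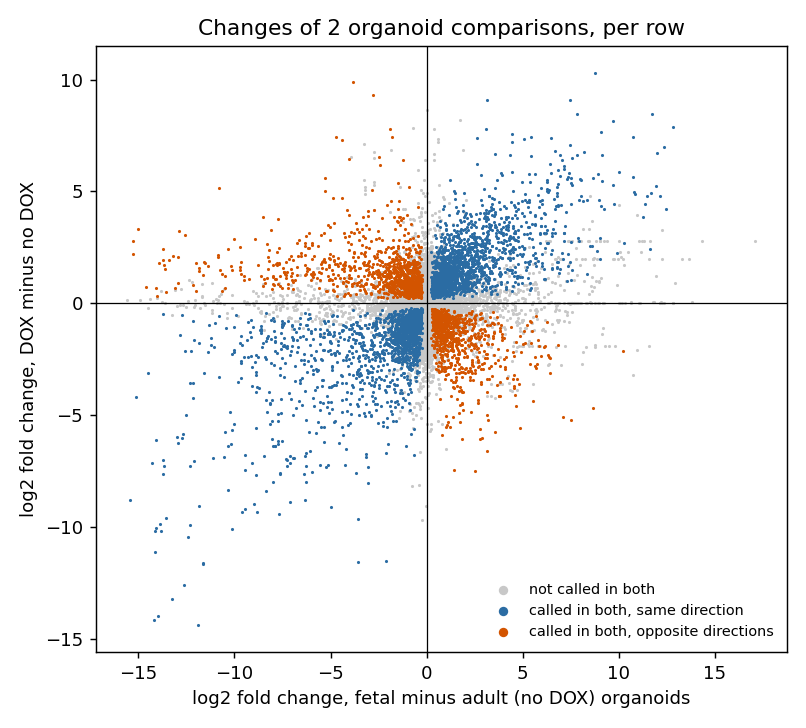
Log2 fold change of each of 14877 organoid rows between DOX and no DOX against that between fetal and no-DOX organoids. Blue rows were called in both with the same direction (3424), orange rows in both with opposite directions (1898), and grey rows were not called in both.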

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

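The leave-out of Rn45s, and of no-DOX libraries for fetal against DOX, was chosen after seeing the data; the other settings were planned. Each setting that was run moved the 4 counts of calls by less than 1.5 times. Over the left-out libraries the counts ran from 7446 to 11416 for DOX against no DOX, 7015 to 10986 for fetal against no DOX, 8810 to 12644 for fetal against DOX and 6397 to 7261 in vivo, and the highest of each organoid range came without no-DOX replicate 3. A fit of only the 2 groups compared gave 7328 for DOX and 6945 for fetal against no DOX, below the main counts of 8785 and 8393. For fetal against DOX it gave 12039, above the main count of 9785. The main fit shares the spread over groups with coefficients of variation of 35.2% without DOX, 8.31% with DOX and 5.59% in fetal organoids. The organoid counts therefore depend on this sharing. DESeq2 gave 9349, 9132, 10143 and, in vivo, 6738, and leaving out Rn45s gave 7321. Library size only turned the sign of 162 calls for DOX and 506 for fetal against DOX. The correlation of the DOX and fetal changes, 0.312, was 0.366 with no filter on low counts and 0.260 for rows with an average log2 CPM of at least 3 (the cause was not tested), and 0.297 to 0.347 over the left-out libraries. Same-numbered libraries did not deviate together (r of −0.36, 0.17 and −0.20 for no DOX and DOX, −0.06, −0.04 and −0.09 in vivo), so the numbers were not read as pairs. Across numbers, no-DOX replicate 3 deviated with DOX replicate 1 (r of 0.35) and against DOX replicate 2 (−0.21). No-DOX replicate 2 deviated against DOX replicate 1 (−0.27), which is not a separate result, because the deviations of a group sum to 0. Whether libraries of the 2 groups share a batch or culture was not tested. With the replicate block the counts were 7985, 7529, 9290 and 6886 and the correlation 0.307. With an estimated correlation 18 of the 23 fixed lists that had passed did not, and the test direction of no list that had passed and the sign of no called named gene turned under any setting, though the median of the immediate early and dissociation stress list went from 0.04 to −0.21 without adult replicate 3. The tests that join both tables were not run under any setting, for want of identifiers in the organoid table. Depth put 3 counts at 0.285 to 0.518 CPM in an in vivo library, which limits statements on rarer genes.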

Other observations

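The gene lists of the next 2 paragraphs and their members were chosen after the in vivo values were seen, and were adjusted over 9 such lists. Their p-values are therefore descriptive and not tests on independent data. Of 20 hypoxia and glycolysis genes 13 were higher in fetal epithelium, or 15 adjusted over the list alone, and 2 lower (camera adjusted p = 7.43e-07, and adjusted p = 0.278 with an estimated correlation). Ndrg1, induced by low oxygen, stood at 1439.7 ± 74.6 against 53.9 ± 9.58 CPM, the oxygen sensor Egln3 was higher by a log2 fold change of 6.21 ± 0.17, the glucose transporter Slc2a1 by 2.12 ± 0.11 and the glycolytic enzyme Pfkl by 2.50 ± 0.13. The 2 lower genes were Car9 at −1.94 ± 0.13 and Hk2 at −0.85 ± 0.10, and 5 genes, among them Ldha and Pkm, were not called. Of 24 lysosome and endocytosis genes 19 were higher and 2 lower (camera adjusted p = 7.43e-07, and adjusted p = 0.278 with an estimated correlation), with the channel Mcoln3 at 7.77 ± 0.22, the sialidase Neu1 at 3.00 ± 0.13 and the endocytic adaptor Dab2 at least 195-fold higher over 0 adult counts. Of 14 bile acid, iron and vitamin transport genes 10 were higher and 3 lower (camera adjusted p = 0.00507, and adjusted p = 0.374 with an estimated correlation), with the iron exporter Slc40a1 at 2.39 ± 0.10, the iron reductase Cybrd1 at 4.39 ± 0.26 and the lipoprotein receptor Scarb1 at 2.47 ± 0.14.

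Nuclear receptors went both ways, 8 higher and 8 lower of 21 (adjusted p = 0.137, median 0.05, mean −0.17, test direction lower), with the vitamin D receptor Vdr at −5.18 ± 0.16 and Ppard at −2.77 ± 0.12. The list passed without adult replicate 2 or 3 (adjusted p = 0.0494 and 0.0397, range over settings 0.0397 to 0.428). Of 14 clock genes 6 were higher and 3 lower (adjusted p = 0.987, median 0.37, mean 0.30, test direction lower), with Nr1d1 at −2.60 ± 0.13, Arntl at −1.53 ± 0.16 and Per2 at 2.10 ± 0.14, and the labels give no time of collection. Of 20 Hedgehog, BMP and Notch genes 10 were higher and 6 lower (adjusted p = 0.131), with Ihh at 1.81 ± 0.10. Of 20 oxidative phosphorylation genes 2 were higher and 8 lower (adjusted p = 0.2204), with Uqcrc1 at −0.72 ± 0.09, and of 22 ribosomal protein genes 7 were lower, or 3 adjusted over the list alone (adjusted p = 0.294), with Rpl5 at −0.91 ± 0.22. All 4 Y-linked genes tested had counts in fetal and 0 counts in adult libraries, with Ddx3y at 29.5 ± 10.7 CPM (camera adjusted p = 2.76e-04, and adjusted p = 0.353 with an estimated correlation), and the labels give no sex. Ddx3y stood at 17.4, 37.7 and 33.4 CPM in fetal replicates 1 to 3. Sex composition therefore changed with age in vivo, and it may differ between the fetal replicates.

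Of the tests that follow, those on the direction of no-DOX replicate 3, the pancreatic genes and the sort gate, and the shared-control draws with the spread of each group, were chosen after the result was seen. For each of the 4 comparisons the 6 libraries make 10 splits, too few for a share under 0.05. As many calls came from 1 split, the real one, with 8785, 8393, 9785 and 7304 calls, and the highest of the other splits gave 0. Each of the other splits mixes libraries of both groups, so the difference between the groups adds to its spread. The 0 calls there therefore carry no weight against chance. The covariance of the DOX and fetal changes, 1.35, lay above all draws with no changed group (highest 0.0468, and 0.104 with the spread of each group). This argues against random spread of the shared controls as its whole source. A shift common to all no-DOX libraries was not part of the draws, so they cannot address it. The correlation of 0.312 and the 59.3% of rows with the same sign lay below the means of both sets of draws.

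Replicate 3 of the organoids without DOX differed over 2-fold from the mean of replicates 1 and 2 in 27.4% of rows, and 49.9% of these were higher. Replicates 1 and 2 thinned to its depth still correlated at 0.993 or more in 20 draws, against at most 0.948 and 0.9505 with replicate 3, which argues against depth. Its deviation had a mean correlation of −0.0275 with the DOX change and −0.0564 with the fetal change across rows, which argues against a leaking transgene and RNA of an induced or a fetal culture as the whole source. Its deviation from the group mean went with that of DOX replicate 1 (r of 0.35) and against those of DOX replicates 2 and 3 (−0.21 and −0.20). A difference in culture or animal stays open and was not tested.

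Pancreatic exocrine genes were higher together in fetal replicate 2. The 12 genes lay above the mean of replicates 1 and 3 by a median of 0.96 (log2, SD 0.263 over genes). This was outside the −0.0966 to 0.0983 that held 95% of 10000 random lists of like expression. Of 4 other lists, 27 enterocyte absorption genes lay inside their random range at 0.03 (−0.0670 to 0.0479). Outside theirs lay 23 enteroendocrine genes at 0.28 (−0.0764 to 0.0725) and 17 mesenchyme genes at 0.22 (−0.125 to 0.158), so a shift was not particular to pancreatic genes. It was smaller in both lists than the 0.96 of the pancreatic genes. Also outside lay 7 gastric genes at −0.65 (−0.268 to 0.322). That value is a difference from the mean of replicates 1 and 3, and Tff1 stood highest in replicate 3. The gastric list therefore need not show a shift of replicate 2. Replicate 2 was picked after its values were seen, and lists of other genes fell outside their ranges as well. The test therefore cannot decide whether the pancreatic genes were transcribed at a steady level in fetal intestinal cells. Pancreatic acinar cells or their RNA carried into the fetal sort are a candidate source, with Ctrb1 at 365, 786 and 329 CPM in replicates 1 to 3, and the gates on CD31 and CD45 would not remove such cells. None of the 12 genes is in another fixed list. Transcription in intestinal cells, whether steady or different between the samples, stays open, as does age.

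Stem cell and Wnt genes were lower in fetal cells, and the adult gate on crypt cells with a middle level of CD24 may take more stem and progenitor cells than the fetal gate. The higher of the medians of these lists was −2.01, and gate and age cannot be told apart for these genes, because all fetal libraries had one gate and all adult libraries the other. For 25 adult-type enterocyte and antimicrobial genes such a gate predicts a median above 0 only if age left them unchanged. A median below 0 therefore cannot exclude the gate. Of these genes, 22 lay below 0, with a median of −4.06 ± 0.770 (SE over genes), but their lists were picked for being lower. The lists of absorption and of suckling-type enterocyte genes had medians of 0.77 and 2.74, so differentiated cells went both ways and gate and age cannot be told apart here either. Age stays open as untested, and sex composition changed with it.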
